A study of Macaca mulatta with 30 samples.

How the data were processed

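The values used are the deposited tables of the authors, 1 of 15521 genes and 1 of 156345 exons, in which each library was scaled by the authors to a common upper quartile, so that the unit is a normalized signal and not a read count. The labels name CASAVA, FastQC, STAR 2.3.0e and edgeR for the steps from the sequencer to these tables. The genome build, the annotation, the program that assigned reads to exons and the base of the coordinates are not given in the sources used here, and exon positions are printed as the exon names give them. Dividing each library by its smallest step returned whole numbers, with 100% of the values within 0.01 of a whole read, 1 read being worth 0.656 to 2.07 normalized reads. Each gene is the sum of its exons, 155 genes and 4074 exons are 0 in all libraries, and the upper quartiles were 587 to 593. The 10 largest genes take 2.93% to 3.30% of a library, and median-of-ratios factors on top of the authors' scaling were 0.994 to 1.01. Symbols were matched to reference tables for 13406 genes.

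All 30 libraries were used, each from 1 animal; the labels speak of 31 animals and 1 outlier removed by the authors. Genes with at least 10 normalized reads in at least 6 libraries were tested (12935 genes), as log2 of the value plus 1, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend), a model of drinking category and cohort, and Benjamini-Hochberg adjustment at 0.05 within each comparison. Differences are given as limma estimates ± SE, and means ± SD are over animals. The comparisons were VHD, HD and BD each against LD, any difference between categories, a trend over LD, BD, HD and VHD scored as equal steps, any difference between cohorts, and cohort 4 against cohort 7a. Because VHD, HD and BD share the LD animals, their differences from LD were not compared with each other. The counts at an unadjusted p under 0.05 are set against 5% of the tested genes. A second count came from edgeR 4.0.16 with TMM factors on the recovered whole reads.

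Exon usage was tested with diffSplice of limma and the Simes method on 118342 exons with at least 5 normalized reads in at least 6 libraries, in 11243 genes with at least 2 such exons. The relative value of an exon is its log2 difference against that of the other tested exons of its gene. Gene lists were fixed before testing: camera of limma, with a correlation of 0.01, was run on 31 lists with at least 5 tested members, and the marker lists of blood cells (1 tested member) and of mitochondrially encoded genes (0) were left out. List scores are the mean z value of the members per animal, compared by permuting animals with scipy 1.17.1 in Python 3.11.15. Figures were drawn with matplotlib 3.10.9. The genes named are those with the smallest p in each direction, 10 for VHD against LD and for the cohorts, 5 for the trend, 3 for HD and for BD, 5 genes for exon usage and 5 for the library sets, together with 20 genes named whatever their value and up to 4 members of a list; other genes are said to be chosen after their values were seen. A few genes within this rule are not reported here, and the counts include them.

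The methods were tested on simulated data made from the means, library sizes and dispersions of the real reads, with 200 genes changed by 1.5, 2 or 4-fold. Recovery of 1.5, 2 and 4-fold changes was 73.1%, 87.9% and 100% for HD, 77.6%, 92.5% and 98.5% for BD, 46.3%, 83.6% and 97.0% for any category, 70.1%, 92.5% and 93.9% for the trend, 63.6%, 89.6% and 98.5% for any cohort, and 74.6%, 92.5% and 100% for cohort 4 against 7a. The share of false calls was 4.68% for VHD, 6.49% for HD, 7.77% for BD, 1.95% for any category, 3.39% for the trend, 7.22% for any cohort and 3.26% for cohort 4 against 7a. Alternatives fixed with the design were pseudocounts of 0.25 and 4, no filter and a minimum of 100, median-of-ratios scaling, a principal component of the marker genes as covariate, array weights, each library left out, no cohort or no category term, only the categories compared, the fit within cohort 7a or 4, lists by an estimated correlation and by rotation (fry), and exon usage with a minimum of 20, a pseudocount of 4 and the F test. Alternatives chosen after the data were seen were a term for 4 sets of 8 consecutive library numbers, edgeR, a term for log2 depth, leaving out 6 libraries under 6 M reads (M, 10 to the power of 6), 1 variance per exon, the estimated correlation without the cohort or category term, and exon usage over the trend.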

Results

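Cortical area 32, a medial prefrontal region, was profiled in 30 male rhesus macaques that had drunk 4% ethanol for over 12 months, with 1 library per animal. The animals fall into low (LD, n = 10), binge (BD, n = 7), heavy (HD, n = 7) and very heavy (VHD, n = 6) drinkers and come from cohorts 4 (n = 9), 5 (n = 8), 7a (n = 8) and 7b (n = 5). The categories are spread unevenly over the cohorts. LD animals come from cohorts 4, 7a and 7b, VHD animals only from cohorts 5 (4 animals) and 7a (2 animals), so VHD and LD meet directly in cohort 7a alone. Cohort 4 was the oldest at the end of drinking, with a mean age of 9.98 years against 7.15, 5.70 and 7.18 years in cohorts 5, 7a and 7b. The libraries hold 4.39 to 13.99 M reads (M, 10 to the power of 6) within the measured exons. Their means are 9.01 ± 2.43 (SD) M in LD, 8.23 ± 3.94 in BD, 9.19 ± 3.16 in HD and 10.2 ± 2.64 in VHD. The first principal component of the 12935 tested genes held 12.9% of the variance and the next 9.71%.

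Very heavy and low drinkers mark the extremes of ethanol intake. AGA and LIPA, which encode lysosomal hydrolases, were 0.76 ± 0.18 and 0.45 ± 0.15 log2 units higher in VHD (limma difference ± SE, n = 6 and n = 10), with AGA at 7.14 ± 0.25 (mean ± SD of log2 normalized reads) in VHD and 6.70 ± 0.33 in LD. DZIP1, whose product sits at the base of primary cilia, differed by 0.42 ± 0.09 (11.22 ± 0.13 against 10.80 ± 0.23), and the lymphotoxin receptor gene LTBR by 0.71 ± 0.23 (7.82 ± 0.22 against 7.12 ± 0.45). GPRIN3, from a family of neurite proteins that bind G proteins, was 0.52 ± 0.14 higher, although 1 VHD library stood apart above the others. HMGB3, which encodes a DNA-binding protein, was 0.49 ± 0.13 higher, with 1 LD library apart at the top of its group. For LIPA 1 VHD library lay apart at the bottom of its group. SUCO, PTPN20B, PLAC9 and TMEM100 followed at 0.31 ± 0.09, 1.54 ± 0.47, 1.06 ± 0.33 and 1.14 ± 0.36. All 6 VHD libraries lay above the LD mean for each of these genes except SUCO and TMEM100, where 5 did.

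Among the genes lower in VHD, the citrate synthase gene CS differed by only −0.18 ± 0.06 but with little spread (10.73 ± 0.07 in VHD, n = 6, against 10.84 ± 0.08 in LD, n = 10). CCNF, which encodes cyclin F, was at −0.44 ± 0.14 and the COPII coat gene SEC31B at −0.26 ± 0.08. The DNA repair gene FANCG was at −0.39 ± 0.13 with 1 LD library apart at the bottom of its group, and TTLL13, from the tubulin ligase family, at −0.96 ± 0.28. SNRPC, which encodes a protein of the U1 splicing particle, was at −1.01 ± 0.33. C18orf21, GIMAP5, SYPL2 and RNF43 were at −0.63 ± 0.16, −1.07 ± 0.31, −0.83 ± 0.27 and −0.56 ± 0.18. All 6 VHD libraries lay below the LD mean for CS, CCNF, SEC31B, FANCG, TTLL13 and SNRPC, 5 did for SYPL2 and RNF43, and 4 did for C18orf21 and GIMAP5. None of these 20 genes passed the test (adjusted p = 0.948 for each). With cohort in the model, limma called 0 of 12935 genes at an adjusted p under 0.05 and 453 at an unadjusted p under 0.05 (228 higher, 225 lower), where chance gives about 647. EdgeR called 0 and 492. The unadjusted count was 813 when VHD replicate 4 was left out, 1046 with array weights, 1063 within cohort 7a and 748 without the cohort term, each with 0 genes at an adjusted p under 0.05. With 6 animals against 10, the same test recovered 54.5%, 91% and 100% of simulated 1.5-fold, 2-fold and 4-fold changes in a trial with 200 changed genes, so small changes in single genes are not excluded.

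**Figure D1:**
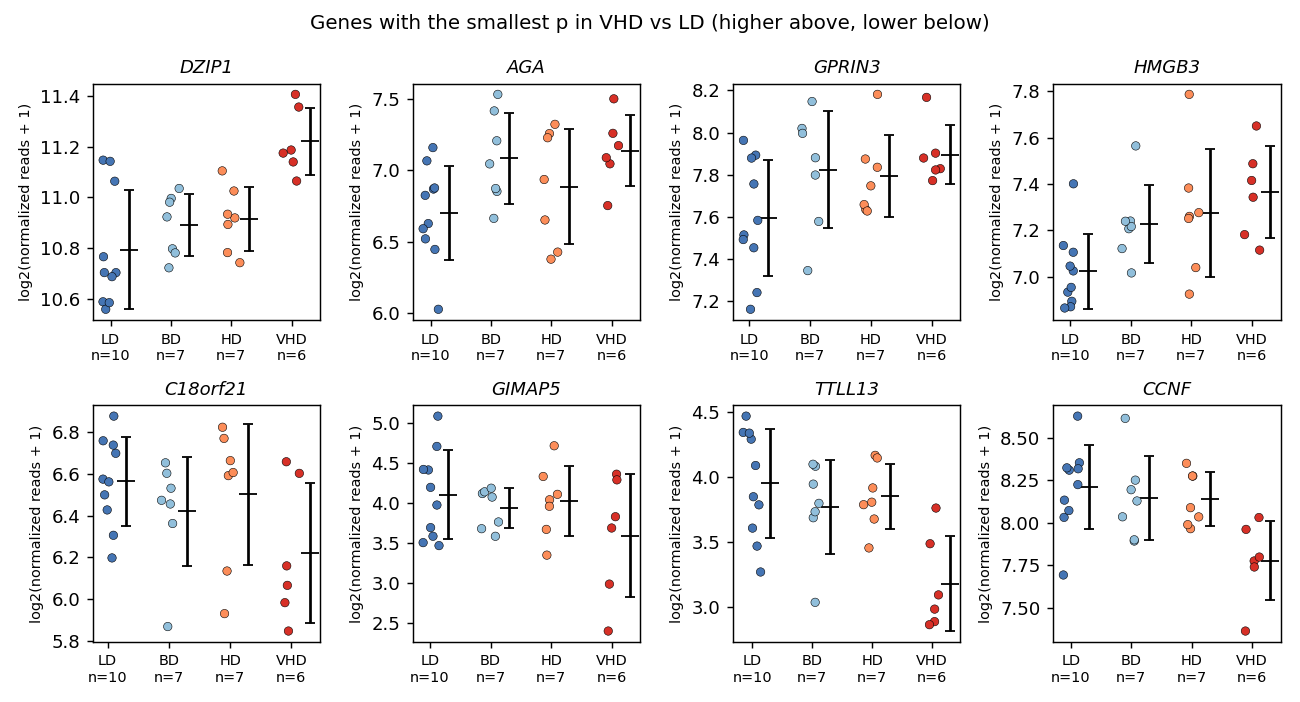
Log2 (normalized reads + 1) of the 4 genes with the smallest p in each direction in VHD against LD, by drinking category (LD n = 10, BD n = 7, HD n = 7, VHD n = 6), with 1 dot per animal and bars of mean ± SD. VHD and LD animals overlap for most of the genes, and BD and HD lie mostly between them.

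Genes with a known place in responses to alcohol, stress or cell type were followed whatever their p-value. In VHD (n = 6) against LD (n = 10) the neuropeptide gene NPY was 0.57 ± 0.25 higher and ALDH2, the mitochondrial acetaldehyde dehydrogenase, 0.22 ± 0.10 higher, and these were the only genes of the 20 at an unadjusted p under 0.05. The growth factor gene BDNF was at 0.36 ± 0.18, and the peptide genes SST, PDYN and CRH at 0.23 ± 0.20, 0.23 ± 0.16 and −0.02 ± 0.18, with 1 VHD library apart at the bottom for CRH. GFAP, which marks astrocytes, was at −0.30 ± 0.17, while the glutamate transporter gene SLC1A2 and the myelin gene MBP were at 0.04 ± 0.06 and 0.18 ± 0.23. The glucocorticoid receptor gene NR3C1 and its regulator FKBP5 were at 0.12 ± 0.09 and 0.02 ± 0.27. Within cohort 7a (2 VHD and 3 LD animals) FKBP5 turned negative, −0.39, and MBP was −0.24. FKBP5 had the same −0.39 when only VHD and LD animals were fitted, as only cohort 7a holds both. Genes of ethanol-sensitive channels and inhibitory transmission, GRIN2B, KCNMA1 and GAD1, stood at −0.05 ± 0.07, 0.05 ± 0.08 and −0.08 ± 0.09. PPM1G, LMO3, NF1, DPF3 and PRKCE stood at −0.13 ± 0.08, 0.15 ± 0.13, 0.05 ± 0.06, 0.03 ± 0.19 and 0.03 ± 0.06. None of the 20 passed the test (adjusted p from 0.948 to 0.994).

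Of the lists of cell markers and pathways, camera called a vessel-wall list and an activity-related list, but only at its preset correlation between genes. The mural and fibroblast markers, which label the vessel wall and meninges, had a median of −0.24 in VHD (n = 6) against LD (n = 10), with 18 of 19 members below 0. NOTCH3 and PDGFRB, receptors of pericytes and smooth muscle, were at −0.28 ± 0.17 and −0.21 ± 0.14, SLC6A13 at −0.42 ± 0.35, and ACTA2 at −0.54 ± 0.42 with 1 LD library apart at the top. The immediate early genes, which neuronal activity induces, had a median of 0.13, with 17 of 22 above 0. NR4A3, NR4A2, BDNF and DUSP6 were at 0.52 ± 0.19, 0.60 ± 0.31, 0.36 ± 0.18 and 0.19 ± 0.13, where 1 VHD library stood apart at the top for DUSP6. With that correlation of 0.01 camera called only these lists of the 31 tested, each at adjusted p = 0.0233. Each had adjusted p = 0.947 with an estimated correlation, where 0 lists were called. No member passed when adjusted over the list alone. The calls depend on the cohort term: without it neither list passed (adjusted p = 0.828 and 0.0628) and camera called the ribosomal proteins (adjusted p = 1.74e-09, 0.731 with an estimated correlation) and the chromatin regulators (0.00797 and 0.731) in their place. With library sets in the model both lists passed, together with the myelin markers (adjusted p = 0.0137) and the oxidative phosphorylation genes (0.0131), but each of these 4 had adjusted p = 0.870 with an estimated correlation. Without the cohort term the vessel-wall list scores were 0.11 ± 0.42 in VHD and 0.14 ± 0.54 in LD, and SLC6A13 was at 0.08.

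The other lists did not pass in VHD against LD (n = 6 and n = 10; adjusted p from 0.117 to 0.969), and their medians ran from −0.08 to 0.16. Among neuronal genes, the excitatory markers had a median of 0.063 (BCL11B 0.30 ± 0.12), and the inhibitory markers −0.076. The glutamate receptors stood at −0.020 (GRIN2C −0.35 ± 0.18) and the GABA and glycine receptors at 0.062. The presynaptic list stood at −0.043 (RIMS3 −0.16 ± 0.08), and the postsynaptic scaffolds at −0.021. The cAMP and calcium enzymes stood at −0.0047 (CAMK2B −0.18 ± 0.08), the potassium channels at −0.025 (KCNIP2 −0.21 ± 0.09), and the calcium and sodium channels at −0.024 (CACNA1G −0.29 ± 0.17). The cadherin and adhesion genes stood at 0.030 (CNTNAP1 −0.21 ± 0.10) and the monoamine, acetylcholine and cannabinoid receptors at −0.019 (HTR7 0.43 ± 0.24). The microtubule and axon genes stood at −0.026 (MAP4 0.22 ± 0.10), and the neuropeptides at −0.018 with a mean of 0.040 and a test direction of up.

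Among glial, vascular and housekeeping genes, the same comparison (n = 6 and n = 10) placed the myelin markers at 0.16 (CLDN11 0.43 ± 0.27) and the astrocyte markers at 0.011 (AQP4 0.29 ± 0.12). The precursor markers stood at −0.011 (VCAN 0.33 ± 0.13), where the mean was 0.0095 and the test pointed down. The microglial markers stood at −0.077, with the macrophage transcription factor SPI1 at −0.67 ± 0.28 and below the LD mean in all 6 VHD libraries. The endothelial markers stood at −0.018 (TIE1 −0.44 ± 0.21) and the choroid and ependymal markers at 0.086 (AQP1 −0.42 ± 0.36). The ribosomal protein genes stood at 0.039 (RPL37 −0.23 ± 0.12, but 0.03 without the cohort term), the oxidative phosphorylation genes at −0.047 (NDUFA10 −0.19 ± 0.07). The chromatin regulators stood at −0.044 (KDM5C −0.17 ± 0.07) and the splicing factors at 0.048 (SRSF2 0.14 ± 0.07). The interferon list was at 0.035 (HMGB1 0.21 ± 0.10) and the glucocorticoid list at −0.0056 (ZBTB16 −0.18 ± 0.12). Cholesterol synthesis stood at 0.022 (CYP51A1 0.19 ± 0.13) and the circadian list at 0.048 (CLOCK 0.14 ± 0.07, with 1 VHD library apart at the bottom). The heat shock list had a median of 0.023, a mean of 0.012 and a test direction of down (CALR −0.19 ± 0.08, with 1 VHD library apart at the top). The ethanol metabolism list had a median of 0.00014, a mean of −0.0026 and a test direction of up. As scores per animal, 0 of the 31 lists passed a permutation test, and 2 had an unadjusted permutation p under 0.05, the chromatin regulators (difference of −0.32, p = 0.0232) and the ribosomal proteins (0.52, p = 0.0397; smallest adjusted p = 0.616).

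In heavy against low drinkers, PTPLA, whose product extends fatty acids, was 0.79 ± 0.17 higher in HD (5.59 ± 0.29, n = 7, against 4.92 ± 0.26, n = 10). The thyroid hormone transporter gene SLCO1C1 was 0.52 ± 0.13 higher and PGAP1, which remodels lipid anchors of membrane proteins, 0.36 ± 0.09 higher. EML2, whose product binds microtubules, was at −0.32 ± 0.07, the citrullinating enzyme gene PADI2 at −0.40 ± 0.09 and TRIP6 at −0.73 ± 0.16. All 7 HD libraries lay on the stated side of the LD mean for each of these genes. None passed the test (adjusted p from 0.20 to 0.298): limma called 0 of 12935 genes and edgeR 0. At an unadjusted p under 0.05 limma called 1623 (759 higher, 864 lower), where chance gives about 647, and edgeR 1518. The HD libraries lie unevenly over the sequence of library numbers, 4 of 7 among the first 8 numbers against 1 of 10 LD libraries, and the unadjusted count was 596 once sets of library numbers entered the model. Without the cohort term 1 gene passed, GPAT2, which was named only because it passed there (−0.93 ± 0.16, adjusted p = 0.0217, against −0.82 and adjusted p = 0.20 with the term).

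In binge against low drinkers, HMGN1, which encodes a nucleosome-binding protein, was 0.44 ± 0.12 higher (BD, n = 7, LD, n = 10), with 1 BD library apart at the bottom. TMEM18 was 0.41 ± 0.12 higher and the somatostatin receptor gene SSTR4 0.86 ± 0.25 higher (4.99 ± 0.58 against 4.08 ± 0.28, all 7 BD libraries above the LD mean). GPR1 was at −1.12 ± 0.29 (all 7 below), the galactokinase gene GALK1 at −0.71 ± 0.20 and TARBP2, which encodes a partner of Dicer, at −0.43 ± 0.12. None passed (adjusted p = 0.999 for each), and limma called 0 of 12935 genes, 394 at an unadjusted p under 0.05 (202 higher, 192 lower), and edgeR 0 and 345. The unadjusted count was 713 without LD replicate 3, 720 without BD replicate 7, 1376 with array weights, 229 at a minimum of 100 normalized reads and 245 within cohort 4. Over all 4 categories at once, limma called 0 genes, 727 at an unadjusted p under 0.05, and edgeR 0 and 668, with a smallest adjusted p of 0.861; the unadjusted count was 1096 without BD replicate 1, 2256 with array weights, 1171 without the cohort term and 376 with library sets in the model.

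A trend over the ordered categories, LD to BD to HD to VHD, uses all 30 animals. AGA had a slope of 0.24 ± 0.06 per category (± SE), followed by GPRIN3, HMGB3, DZIP1 and SUCO at 0.17 ± 0.04, 0.16 ± 0.04, 0.12 ± 0.03 and 0.11 ± 0.03. CD93, an endothelial receptor gene, had a slope of −0.28 ± 0.08, the transcription factor gene GLIS3 −0.18 ± 0.05, and NAPA, which encodes the SNARE recycling protein alpha-SNAP, −0.11 ± 0.03. GLIS3 stood at 7.29 ± 0.20 in LD, 7.13 ± 0.26 in BD, 6.74 ± 0.18 in HD and 6.85 ± 0.18 in VHD, lowest in HD. C18orf21 and FANCG had slopes of −0.19 ± 0.05 and −0.15 ± 0.04, with 1 BD library of C18orf21 and 1 HD library of FANCG apart from their groups. None of these passed (adjusted p = 0.745 for each). Limma called 0 of 12935 genes, 799 at an unadjusted p under 0.05 (403 higher, 396 lower), and edgeR 0 and 814; the unadjusted count was 501 to 517 when LD replicate 8, LD replicate 2 or BD replicate 6 was left out. It was 1853 with array weights, 1460 without the cohort term and 405 with library sets in the model. The slope differed between cohorts for 0 genes (290 unadjusted by limma, smallest adjusted p = 1.0).

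Over the trend 3 lists were called. The mural and fibroblast markers had a median slope of −0.15 per category with 18 of 19 members below 0 (n = 30), the immediate early genes 0.039 with 17 of 22 above 0, and the splicing factors 0.022 with 36 of 43 above 0. The mural markers did not fall step by step: their medians against LD were −0.0038 in BD, −0.73 in HD and −0.24 in VHD. These 3 lists passed at adjusted p = 0.000567, 0.0348 and 0.0331, against adjusted p = 0.901 for each with an estimated correlation, and no member passed when adjusted over the list alone. With library sets in the model the splicing factors lost their call (median slope of 0.0048, adjusted p = 0.593), while the mural list stood at −0.094 (adjusted p = 0.00193, against 0.890 with an estimated correlation). Without the cohort term all 3 lost their call, and the ribosomal proteins (adjusted p = 1.17e-08), the oxidative phosphorylation genes and the chromatin regulators (each 0.00690) were called, each at 0.868 with an estimated correlation. In lists with medians near 0 the summaries disagree in sign: the astrocyte list had a median of 0.0050, a mean of −0.0055 and a test direction of down, the myelin list 0.014, 0.00090 and down, the precursor list 0.0049, 0.0034 and down, the neuropeptides −0.0035, 0.021 and up, and the ethanol metabolism list −0.0070, −0.0088 and up.

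Exon usage gave calls where whole genes did not. In the phosphatase gene PTPN11 the exon at chromosome 12, 111892191–111892287, was at 6.11 ± 0.78 (mean ± SD, VHD, n = 6) against 4.79 ± 0.38 (LD, n = 10), a log2 difference of 1.62 relative to the other tested exons of the gene (adjusted p = 1.43e-07). The transcription factor gene ATF2 (chromosome 2b, 62104107–62104263; 1.93, adjusted p = 4.3e-08) and the adaptor coat gene AP1B1 (chromosome 15, 71146925–71147084; 2.24, adjusted p = 6.48e-09) were called on exons of few reads, with 10 and 8 LD libraries under 5 normalized reads. HERC1, a large ubiquitin ligase gene, was called for a relative difference of −1.26 at chromosome 14, 40361308–40361429 (adjusted p = 8.49e-09, but 0.116 without the cohort term).

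The exon test of diffSplice, which shares 1 variance among all exons of a gene, called 100 of 11243 genes in VHD against LD (n = 6 and n = 10; 691 at an unadjusted p under 0.05), and 172 over the trend (870 unadjusted, n = 30). With 1 variance per exon it called 0 genes in each comparison (287 unadjusted in VHD against LD), with adjusted p = 1.0 for PTPN11. In simulated data with 200 exons changed 4-fold it recovered 87% of them, but 23.7% of its 228 calls were false, and it made 27 calls in data with no change. The exon calls therefore name places to look at and are not counted here as changes.

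**Figure D2:**
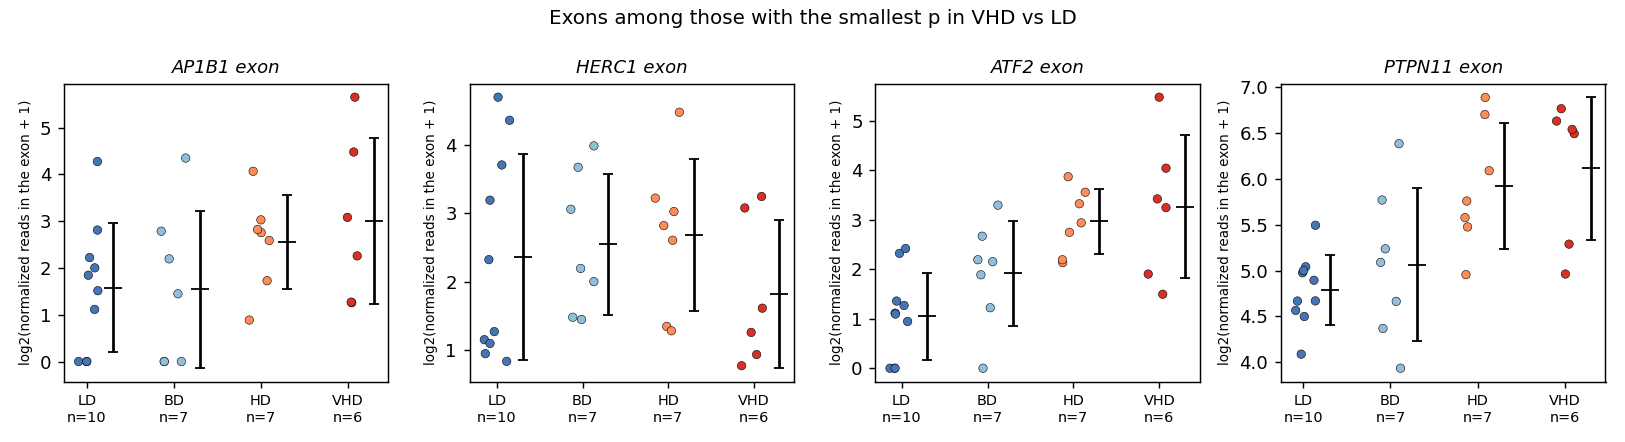
Log2 (normalized reads in the exon + 1) of the exon behind exon usage calls with the smallest p, in 4 genes, by drinking category (LD n = 10, BD n = 7, HD n = 7, VHD n = 6), with 1 dot per animal and bars of mean ± SD. PTPN11 separates most VHD from LD animals, with some BD and HD animals as high as VHD, while the other 3 exons hold few reads.

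Cohort 4, the oldest, was compared with cohort 7a, the youngest, with drinking category in the model. LRRC1 was 0.83 ± 0.18 higher in cohort 4 (6.39 ± 0.28, n = 9, against 5.58 ± 0.43, n = 8), and the myelin transcription factor gene MYRF 0.96 ± 0.22 higher (8.27 ± 0.56 against 7.31 ± 0.28). The oligodendrocyte receptor gene S1PR5 was 1.27 ± 0.31 higher and STAT2, a signal carrier of interferon, 0.29 ± 0.06 higher, with 1 cohort 4 library apart at the top. ADAMTS16, ANP32B, SEMA4F, C2orf88, PNLDC1 and TAF1D followed at 0.65 ± 0.15, 0.36 ± 0.08, 0.36 ± 0.08, 0.45 ± 0.11, 1.93 ± 0.47 and 0.35 ± 0.08. For PNLDC1, 1 cohort 7a library stood apart at a value of 0. The nicotinic receptor gene CHRNA2 was at −1.09 ± 0.22 (5.38 ± 0.59 against 6.26 ± 0.50), with 1 cohort 7a library apart at the bottom. The heparan sulfate enzyme gene HS6ST3 was at −0.28 ± 0.06, the kinase gene CAMK4 at −0.47 ± 0.11 and the potassium channel subunit gene KCNV1 at −0.41 ± 0.10. LDLRAD4, ARHGEF10, KIAA1467, FREM3, TMEM178B and HIVEP2 stood at −0.27 ± 0.06, −0.34 ± 0.07, −0.34 ± 0.07, −0.58 ± 0.13, −0.23 ± 0.05 and −0.27 ± 0.06. For FREM3, 1 cohort 4 library stood apart at the bottom. Of the 9 cohort 4 libraries, 8 lay on the stated side of the cohort 7a mean for SEMA4F, CHRNA2 and ARHGEF10, and 9 did for the other genes.

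None of these cohort genes passed the test (adjusted p from 0.144 to 0.147). Limma called 0 of 12935 genes between cohorts 4 and 7a (n = 9 and n = 8), 1183 at an unadjusted p under 0.05 (639 higher, 544 lower), and edgeR 0 and 1117. Over all 4 cohorts limma called 0 genes, 1040 unadjusted, and edgeR 0 and 1059, with a smallest adjusted p of 0.167. The genes followed whatever their p-value ran from −0.41 ± 0.15 (CRH) to 0.62 ± 0.19 (MBP), with PDYN at 0.48 ± 0.13 and 7 of the 20 at an unadjusted p under 0.05 (adjusted p from 0.174 to 0.998). The calls depend on the model and on single animals: 26 genes passed without the category term, 15 with library sets in the model, 7 without BD replicate 1 (ADAMTS15, CHRNA2, FREM3, HS6ST3, KIAA1467, LDLRAD4 and LRRC1, chosen after their values were seen) and 1 without LD replicate 9 (CHRNA2, −1.22, adjusted p = 0.0271). Age and cohort cannot be told apart, because the labels give 1 mean age per cohort.

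The myelin list had the largest median difference of the 31 lists between these cohorts. The 25 oligodendrocyte and myelin markers were all higher in cohort 4 (n = 9) than in cohort 7a (n = 8), with a median of 0.68 and quartiles of 0.50 and 0.88. The structural myelin genes MBP and MAG were at 0.62 ± 0.19 and 0.84 ± 0.25, and ERMN and PLLP at 1.04 ± 0.32 and 0.69 ± 0.21. The mean log2 value over the list was 7.77 ± 0.56 (SD) in cohort 4, 7.33 ± 0.54 in cohort 5, 7.11 ± 0.25 in cohort 7a and 6.98 ± 0.16 in cohort 7b. The list passed at adjusted p = 3.31e-19, against adjusted p = 0.152 with an estimated correlation, and 19 members passed when adjusted over the list alone. As a score per animal the list stood at 0.70 ± 0.95 in cohort 4 and −0.38 ± 0.38 in cohort 7a, with an exact permutation p of 0.00469 (0.0536 adjusted over the 31 lists).

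**Figure D3:**
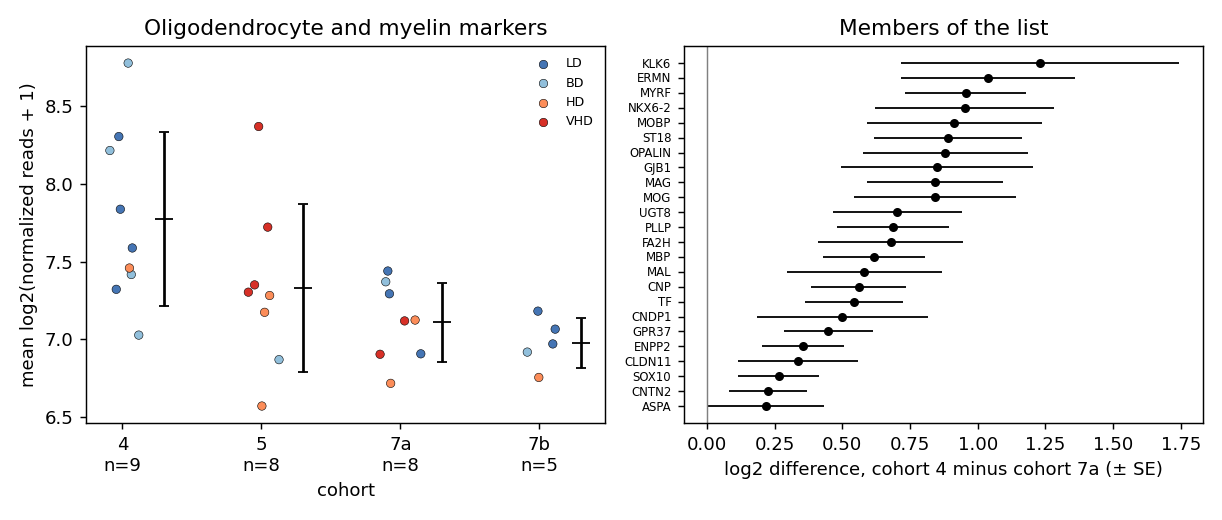
Left, mean log2 (normalized reads + 1) over the 25 oligodendrocyte and myelin markers by cohort, with 1 dot per animal coloured by drinking category and bars of mean ± SD; right, the log2 difference ± SE of single markers between cohorts 4 and 7a. Every marker shown lies above 0, and animals of cohort 4 spread widely.

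Several neuronal and activity-related lists had lower medians in cohort 4 (n = 9) than in cohort 7a (n = 8), and of these calls only 1 also held at an estimated correlation. The cAMP and calcium enzymes, which relay receptor signals, had a median of −0.067 with 26 of 33 below 0 (adjusted p = 0.00186), the only list also called with an estimated correlation (adjusted p = 0.0349) and by rotation (0.0145). With library sets in the model it lost its call at an estimated correlation (adjusted p = 0.0575), as it did without the category term (0.0578). Its score, tested after its values were seen, was −0.16 ± 0.18 against 0.20 ± 0.15 (exact permutation p = 0.000987, 0.0306 adjusted), and CAMK4 passed when adjusted over the list alone. The immediate early genes had a median of −0.20 (18 of 22 below 0; adjusted p = 2.36e-05, 0.152 with an estimated correlation), and EGR2, DUSP6 and SIK1 passed over the list alone at −0.58 ± 0.17, −0.37 ± 0.11 and −0.42 ± 0.12. Inhibitory neuron markers stood at −0.099 (17 of 23; 0.000408 and 0.228), led by NDNF at −0.54 ± 0.16. Circadian genes stood at −0.10 (16 of 18; 0.00186 and 0.133), led by the clock repressor gene PER2 at −0.32 ± 0.10. The potassium channels stood at −0.10 (20 of 26; 0.00613 and 0.152), the calcium and sodium channels at −0.14 (10 of 15; 0.0149 and 0.152). The cadherins stood at −0.059 (33 of 46; 0.0149 and 0.266) and the postsynaptic scaffolds at −0.042 (17 of 23; 0.0180 and 0.485). The sign of the summaries differed for the excitatory markers (median of −0.0073, mean of 0.0032, test direction of up) and the GABA receptors (−0.069, 0.0099 and down).

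Metabolic, vascular and immune lists were also called between these cohorts (n = 9 and n = 8), though none of them at an estimated correlation. The oxidative phosphorylation genes were lower in cohort 4 with a median of −0.087 (59 of 70 below 0; adjusted p = 1.23e-05, 0.152 with an estimated correlation). The mural and fibroblast markers stood at −0.18 (12 of 19; 0.0180 and 0.537; scores per animal of −0.10 and −0.0046, exact permutation p = 0.718) but split within the list, where 7 members were lower and 2 higher when adjusted over the list alone. Among these were the collagen genes COL1A1 and COL1A2 at −1.62 ± 0.40 and −1.28 ± 0.37, the growth factor gene IGF2 at −1.08 ± 0.29 and NOTCH3 at 0.46 ± 0.14. The glucocorticoid list stood at −0.083 (10 of 18; 0.0207 and 0.266), with KLF9 at −0.33 ± 0.09 passing over the list alone. Cholesterol synthesis was higher at 0.11 (16 of 22; 0.0207 and 0.558), as was the interferon list at 0.097 (21 of 31; 0.0226 and 0.424), with STAT2 passing over the list alone. In all, 14 of 31 lists were called, of which 1 remained with an estimated correlation. Without the category term 9 lists were called, and the mural, postsynaptic, calcium and sodium channel, glucocorticoid, cholesterol and interferon lists were not among them. With library sets in the model no list was called at an estimated correlation; the mural list stood at −0.38, the glucocorticoid list at −0.13 and cholesterol synthesis at 0.066.

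More genes were called between library numbers than between categories or cohorts, in a test chosen only after the values were seen. The numbers in the library names run to 32, and libraries 1–8 (n = 8) differed from the other 22. TMEM107, a gene of the ciliary transition zone, was 1.58 ± 0.10 higher in the first 8 (9.23 ± 0.24 against 7.57 ± 0.19), and the DNA polymerase subunit gene POLA2 1.30 ± 0.14 higher. The ribosomal protein gene RPL41 was 0.82 ± 0.11 higher, and VAMP4 and FBXO11 0.56 ± 0.07 and 0.31 ± 0.04 higher. SGSM3, RUSC2, DEF8, LRRC14 and PSD fell, by 0.53 ± 0.05, 0.37 ± 0.04, 0.46 ± 0.06, 0.67 ± 0.08 and 0.44 ± 0.06. The TMEM107 excess lies in 1 exon, at 8107468–8108324, which was 2.14 ± 0.12 higher while the other 4 were at −0.31 to −0.75. A small nucleolar RNA gene lies in the 3′ untranslated end of human TMEM107, and that exon would count its reads if the same holds in the macaque. Between 4 sets of 8 consecutive numbers, with category and cohort in the model, limma called 2778 genes, and between the first 8 and the rest 2010 (823 higher, 1187 lower).

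**Figure D4:**
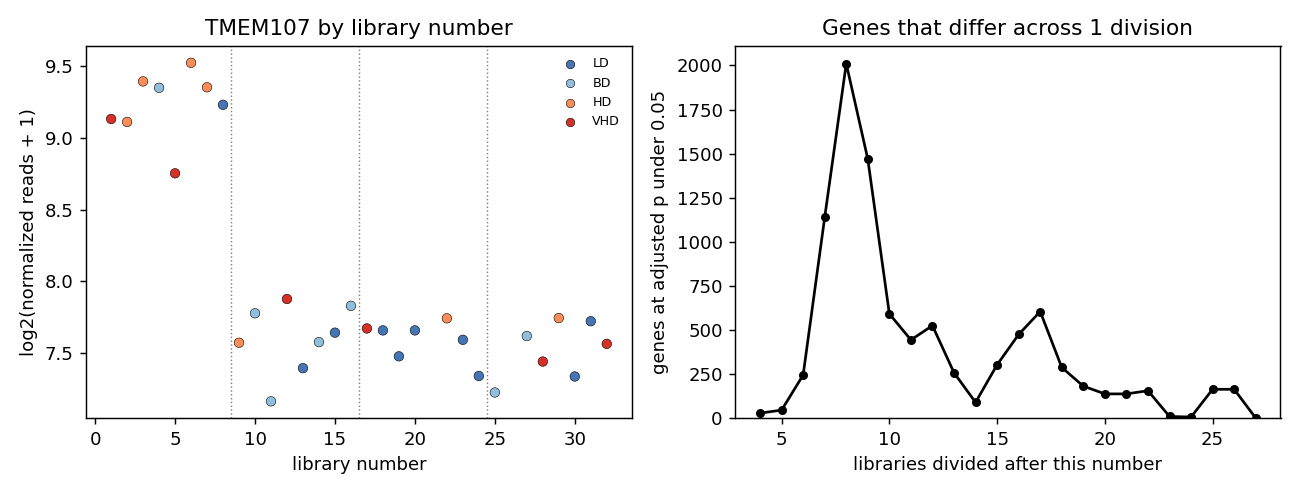
Left, log2 (normalized reads + 1) of TMEM107 against the library number, with 1 dot per animal coloured by drinking category and dotted lines between the sets of 8; right, the number of genes at an adjusted p under 0.05 when the libraries are divided once after each number. TMEM107 steps down after library 8 in every category, where the number of genes also peaks.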

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

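Tests chosen only after the result was seen were the shuffles of library numbers, the length measure with category and cohort in the model and by cohort, the removal of a length trend, the set term in the HD counts and in the exon calls, 1 variance per exon, and for the myelin markers the correlation between genes, the other glial markers and the label splits.

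In 20 of 274 groups of named genes, in 3 of 64 groups of list scores and in 1 group of depths, 1 library lay apart from its group, where chance singles out about 1 in 20 groups; the values below are its gap to the nearest library as a share of the range of the group. LD replicate 1 was highest for HMGB3 (0.497) and ACTA2 (0.694) and lowest for FANCG (0.523) and the astrocyte score (0.473). LD replicate 2 was lowest in cohort 7a for PNLDC1 (0.562) and PDYN (0.532), and LD replicate 3 was lowest in LD for log2 depth (0.47). VHD replicate 3 was highest for GPRIN3 (0.67) and lowest for CRH (0.632), and VHD replicate 4 highest for CALR (0.73) and lowest for CLOCK (0.639). VHD replicate 5 was lowest for LIPA (0.683) and highest for DUSP6 (0.663) and the circadian score (0.663), and VHD replicate 6 lowest for the postsynaptic score (0.677). Among BD libraries, replicate 3 was highest for HMGB3 (0.592), replicate 5 lowest for C18orf21 (0.629) and replicate 7 lowest for HMGN1 (0.594), and within cohort 4 BD replicate 7 was highest for STAT2 (0.672) and lowest for FREM3 (0.494). HD replicate 2 was highest for FANCG (0.648), and HD replicate 6 was lowest in cohort 7a for CHRNA2 (0.611) and PPM1G (0.53).

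Each count was set against 100 labellings, the real one and shuffles of categories within cohorts or of cohorts within categories, and the values are how many labellings reached the real count. Chance is not excluded for genes at an unadjusted p under 0.05 in VHD against LD (63 labellings; real count of 453, highest other 2252), HD (5; 1623, 2925), BD (65; 394, 3284), any category (32; 727, 3031), the trend (26; 799, 1903), any cohort (8; 1040, 1876) and cohort 4 against 7a (8; 1183, 3059). It is not excluded for exon usage in VHD against LD (83; 100, 1182) and over the trend (38; 172, 1218), nor for lists in VHD against LD (91; 2, 14) and over the trend (80; 3, 15). For lists between cohorts 4 and 7a, 3 labellings reached the real count, the real labelling among them (real count of 14, highest other 16). This is fewer than for the other counts, but with no adjustment for the number of counts tested, chance is not excluded here either. Some labellings called several times the real count, and whether a structure of the samples other than category and cohort lies behind this was not tested.

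Between the 4 sets of library numbers 2778 genes differed, and of 100 groupings only the real one reached that count (1; 69 in the highest shuffle). Depth, drinking category and a trend over transcript length are argued against as the whole source. With log2 depth in the model 1864 genes were called, and 2664 once the length trend was taken out of each library (53 in the highest shuffle). Category was already in the model behind the 2778 genes. Within LD and BD alone 1605 were called, but there the first set holds only 1 LD and 1 BD library, and no shuffles were run. The overlap of these genes with the 2778 was not counted. A difference in preparation or sequencing of the first 8 libraries may account for these steps, and a loss of short transcripts as a part of it stays open, since the shortest 10% of genes against the longest 10% stood at −0.0772 ± 0.0253 there with category and cohort in the model, within its error of the bound of 0.1 (−0.0432 and exact permutation p = 0.170 over all libraries, p = 0.0141 permuting within cohorts); boundaries after libraries 1, 9, 17 and 25 gave 2910 genes and boundaries moved by 1 number gave 524. Library sets may also account for the HD excess, as 4 of 7 HD and 1 of 10 LD libraries are in the first set: with the set term the HD count was 0.922 times the number chance gives, lower than with any of 99 shuffled set terms (lowest 664, median 1448). The shuffles do not keep the overlap of the first set with HD. They therefore cannot tell an effect of the sets from a drinking effect that the set term takes up. The median difference of the 1623 genes went from 0.27 to 0.17, against a median SE over all genes of 0.115 and 0.113. The SE of the 1623 genes alone was not compared, so a loss of precision for them is not excluded. An effect of heavy drinking on single genes is not excluded either.

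The exon usage calls have more than 1 reading. The test treats exons of a gene as independent with a shared variance, and over the shuffled labellings it made a median of 139 calls (at least 68), more than the 100 real calls, which is in line with calls that arise from the test and not from VHD. With 1 variance per exon 0 genes were called, although that form recovered 82% of simulated 4-fold exons. With the set term the same test called 73 of the 100 genes again. Because that test also calls genes in shuffled labellings, this cannot decide whether library sets play a part.

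Myelin markers were higher in cohort 4 than in cohort 7a by a median of 0.679, which only the real labelling of 100 reached. The other labellings ran from −0.610 to 0.529. The list has the largest median difference of the 31 tested, which this count does not allow for. Some shuffled labellings gave the list a smaller camera p than the real 1.07e-20, down to 3.01e-25, so chance is not excluded by that measure. Library sets are argued against as the source, as 0.80 remained with the set term (camera adjusted p = 0.108 with an estimated correlation). They are not excluded, since the first set holds 0 libraries of cohort 4 and 3 of cohort 7a, and the sets were chosen after the values were seen. A lower share of neurons with all glia raised alike is excluded, since the astrocyte, microglial and precursor lists had medians of 0.0476, −0.0847 and 0.0501. More white matter in some cohort 4 pieces may explain the difference, and the markers moved together with a correlation of 0.648 between genes. Markers of 1 cell type could move together whatever changes their amount, so this correlation does not tell white matter from age. The neuron markers had a median of −0.085, though the excitatory markers alone stood at −0.0073. The age of cohort 4 could also raise myelin genes, and this was not tested because age and cohort cannot be told apart.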

How the results depend on the processing

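The gene, list and exon results were refitted under the other settings, most of them chosen before the data were examined and the library set term, edgeR, depth, library exclusion, per-exon variance and the estimated correlation without the cohort or category term chosen afterwards. No paired analysis was possible because the labels give no replicate numbers shared between categories, and each library is 1 animal. A value is said to stay if it keeps its side of the 0.05 threshold, whatever the size of the change. A change of sign counts as reversed only where the value exceeds its SE in either fit. Because no gene passed in the main fit of these comparisons, a value stays by again not passing. The counts of values that stayed therefore do not show that the differences are stable. Of 1749 values for 134 pairs of a named gene and a comparison, 1726 stayed, 17 passed the test only in the other setting and 6 reversed. The reversals were SLC6A13 and RPL37 without the cohort term (0.0764 and 0.0305), MBP within cohort 7a (−0.238), FKBP5 within cohort 7a and with only VHD and LD (−0.388), and GAD1 between cohorts 4 and 7a without libraries under 6 M reads (0.0208). The FKBP5 values are 1 contrast of 2 VHD and 3 LD animals, since only cohort 7a holds both categories. Of 4020 values with a library left out, 4013 stayed, 7 newly passed and 0 reversed. Among those that stayed, PRKCE between cohorts 4 and 7a ran from −0.0205 to 0.0395, on both sides of 0. The counts of 0 genes became 1 for HD without the cohort term (GPAT2), 1 for any cohort with the set term (CDH19), and 26 without the category term and 15 with the set term for cohort 4 against 7a, where leaving out a library gave 0 to 7. Array weights raised the unadjusted VHD count to 1046 with 0 adjusted. The 2 lists called in VHD against LD became 0 with an estimated correlation, 0 by rotation, 4 with the set term and 0 with the set term and an estimated correlation, and without the cohort term 2 other lists were called, or 0 with an estimated correlation. The list scores, which permute animals and hold no cohort term, gave 0 calls where camera with the cohort term gave 2. The 3 lists of the trend became 0 with an estimated correlation, 0 by rotation, 2 with the set term, 0 with the set term and an estimated correlation, and without the cohort term 3 others, or 0 with an estimated correlation. The 14 lists of the cohorts became 1 with an estimated correlation, 1 by rotation, 9 without the category term and 0 without it at an estimated correlation. With the set term they became 19, or 0 with the set term and an estimated correlation. Of 95 list calls over the settings, 47 were kept, 48 lost and 0 reversed. The 100 exon usage genes of VHD against LD became 252 without the cohort term, 45 with a pseudocount of 4, 8 by the F test and 0 with 1 variance per exon, with or without the set term. The 172 of the trend became 501, 81, 11, 0 and 0 in the same settings, and 98 at a minimum of 20 reads.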

Other observations

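Lists in HD against LD (n = 7 and n = 10), were looked at after their values were seen. The mural and fibroblast markers had a median of −0.73 (adjusted p = 1.83e-07, against adjusted p = 0.586 with an estimated correlation) and the myelin markers −0.25 (0.000623 and 0.786), while the splicing factors stood at 0.077 (0.00653 and 0.691), the GABA and glycine receptors at 0.11 (0.0172 and 0.586) and the cadherins at 0.051 (0.0130 and 0.586). With the library set term the mural list stood at −0.50 (6.61e-08, 0.721 with an estimated correlation) and the myelin list at −0.24 (3.48e-05 and 0.721). The splicing factors, at 0.0050 (adjusted p = 0.855), and the GABA and glycine receptors and the cadherins, at 0.055 and 0.028 (0.135 each), were no longer called. In BD against LD (n = 7 and n = 10) only cholesterol synthesis was called, with the set term alone (−0.091, adjusted p = 0.0412, 0.998 with an estimated correlation).

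With the set term, 15 genes passed between cohorts 4 (n = 9) and 7a (n = 8), named here after their values were seen. In cohort 4 the collagen genes COL1A1 and COL1A2, with PCOLCE, IGF2 and CYP26B1, were lower, at −1.95 ± 0.34, −1.65 ± 0.34, −1.36 ± 0.26, −1.25 ± 0.25 and −1.18 ± 0.24 (limma difference ± SE), and ADAMTS15, KIAA1199, HS6ST3 and KIAA1467 were lower too. CDH19, BCAS1 and VCAN were higher by 0.84 ± 0.16, 0.76 ± 0.15 and 0.48 ± 0.10, as were LRRC1, CAST and ANP32B (adjusted p from 0.0408 to 0.0494).

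Of all tested genes, 3 fell into 2 separate ranges over the 30 animals with a gap above 2 log2 units, against 0 in simulated normal values. IFIT1B was at most 3.36 in 7 animals and at least 6.38 in 23, SIRPB1 at most 2.03 in 13 and at least 4.90 in 17, and TDRD5 at most 3.26 in 13 and at least 5.49 in 17. The low range of each gene starts at 0, a floor that the simulated normal values do not have. In cohorts 4, 5, 7a and 7b (n = 9, 8, 8 and 5) the high range held 7, 5, 7 and 4 animals for IFIT1B. It held 7, 5, 2 and 3 for SIRPB1 and 7, 7, 2 and 1 for TDRD5. Cohort 4 against 5 and against 7b gave myelin medians of 0.45 and 0.76 (adjusted p = 0.400 and 0.0681 with an estimated correlation), cohort 5 against 7a and 7b gave 0.22 and 0.29, and cohort 7a against 7b gave 0.052. Mean depth over the 4 sets of library numbers was 7.78, 6.87, 9.49 and 12.8 M reads (M, 10 to the power of 6).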
